A study of Mus musculus with 8 samples.

How the data were processed

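Total RNA of 8 neurosphere cultures was measured, 1 array each. Per the labels' protocols, EBs were dissociated on day 6 and plated with lentivirus at an MOI of about 25, grown with 20 ng/ml FGF2, and 50 ng of RNA was labelled with Cy3. The labels do not say whether the cultures were grown independently, and all 8 arrays lay on 1 slide scanned once, per the file headers. The shRNA arrays lay in slide column 1 and the miRNA arrays in column 2, so gene values alone cannot tell vector system from column, and slide row goes with passage and treatment.

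The arrays were Agilent SurePrint G3 mouse arrays, read with Feature Extraction 10.7.3.1, per the file headers. The deposited scanner files give intensity per spot, detrended and background-subtracted, with surrogate values for dim spots, per the file headers. Each array has 62976 spots, of which 59305 are not controls and cover 55681 probes. The authors also deposited a table of signal values, which equals that intensity divided by 1 constant per array (481 to 949, close to the array's 75th percentile). The table is linear and was not centred by gene, and its column medians were 0.0662 to 0.124. How its constants were chosen is not given in the sources used here. Coordinates are mm9, the build named in the file headers. The reference table used for gene names was GRCm38.p6, and none of its coordinates were used.

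Control spots and the 1104 spots flagged as outliers by the image software were left out, and the 28 probes left with no spot on some array were dropped, which left 55653 probes. Intensities were put on the log2 scale, averaged over a probe's spots, and each array's log2 75th percentile over non-control spots was subtracted. A probe was kept if well above background on at least 2 of 8 arrays (39640 probes). For the 7867 genes with several such probes, the probe with the highest mean was used. In bounds and counts of arrays, a gene was taken as well above background on an array where any of its probes was. Probes were named through their accession where the reference held it (26407), and 25256 kept the name in the file. The upper-quartile intensity was 530 to 1065 per array, and the median coefficient of variation over probes printed 10 times was 4.75% to 5.18%, which describes spot noise, not culture noise. In 11 called passage genes probes disagreed in direction by over 1.5-fold.

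All choices in this paragraph were made before the data were examined. limma 3.58.1 in R 4.3.3 was fitted with condition and passage as factors, giving 3 residual degrees of freedom (2.21 prior). This residual also holds any real interaction. Benjamini-Hochberg adjusted p under 0.05 over 27255 genes was called, two-sided. A second fit with 1 residual degree of freedom (3.08 prior) tested the interaction of knockdown or miR-17 with passage. Single arrays were compared as differences with no test and counted at 2-fold. A probe not well above background on every array of a group gives only a bound, the bright group's mean against the higher of the array's lowest signal well above background and the probe's own. Fold changes given as "at least" use it, and where part of the arrays of the lower group were dim, the dim ones were set in the same way.

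In all, 27 gene lists with 550 genes were written beforehand: neural stem, early-stage temporal, gliogenic, astrocyte, oligodendrocyte, proneural, neuron, motor neuron, interneuron, Hox, forebrain, dorsoventral, pluripotency, mesoderm and endoderm, crest and mesenchyme, endothelial and blood, surface ectoderm, cell cycle, JAK-STAT, BMP and TGF-beta, Notch, interferon, p53, reported miR-17 targets, Nr2f family, hypoxia and unfolded protein genes. They were tested in camera with a preset correlation of 0.01, and with an estimated one, adjusted over the 81 tests of lists and effects. The form with an estimated correlation also uses only the 3 residual degrees of freedom. It therefore has little power here, whatever the correlation. For single arrays a list's median was placed among 10000 random lists matched on mean level in 20 bins. The genes named were taken from 12 up and 12 down for each effect, by size among called genes moving the same way in every pair. Where too few passed, these were filled with uncalled genes in order of their smallest difference over the pairs. Also named were Nr2f1 and Nr2f2, up to 4 members per list with the largest difference in the comparison at hand, the 6 highest and lowest genes that differed in that direction at 1 passage only, and up to 12 regulators per manipulation that moved back toward P0. Genes with placeholder names were not used, and not all genes picked in these ways are printed.

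Alternatives were normexp background correction (offset 50), quantile normalization, no filter and a filter on all 8 arrays, the mean of a gene's probes, the authors' table, a trended prior, each array left out in turn, no block, control conditions only, each vector system alone, other fold limits, other gene definitions for the return toward P0, and an estimated correlation in camera. The procedure was tested on simulated data with 27255 genes. Passage changes of 2-, 4- and 16-fold were recovered in 0 of 67, 26 of 67 and 59 of 66 cases. With 40% of genes changed at 4-fold, 95.0% of 10902 were recovered and 299 unchanged genes were called. Knockdown changes were recovered in 0, 0 and 51 of 66 cases and miR-17 changes in 0, 4 and 52 of 66. A match of 3' UTRs to the miR-17 seed was not run, since no transcripts were used here. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 read the files and drew the plots.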

Results

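RNA from mouse neurospheres was measured on 8 single-colour arrays, each read in the Cy3 channel. The neurospheres, floating clusters of neural stem and progenitor cells, were grown from the mouse embryonic stem cell line EB3 through embryoid bodies formed with Noggin, an inhibitor of BMP signalling. Primary neurospheres (P0) were collected after 6 days in FGF2, and tertiary neurospheres (P2) after further rounds of dissociation and regrowth. At each passage 4 lentiviral conditions were measured: a control shRNA against luciferase, an shRNA against Nr2f1 and Nr2f2, a control miRNA, and miR-17. This gave 8 groups with 1 array each, so a difference between 2 arrays of the same passage had no replicate check. Between 57.9% and 67.9% of non-control spots lay well above background, and no non-control spot was saturated. After filtering, 27255 genes were compared, and the small number of arrays limited the precision of every comparison.

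The first comparison checked the knockdown on its targets, the orphan nuclear receptors Nr2f1 and Nr2f2 (COUP-TFI and COUP-TFII). Nr2f1 was read by 2 probes, on chromosome 13 at 78328723 to 78328782 and at 78328290 to 78328349 of mm9, and Nr2f2 by 1 probe on chromosome 7 at 77496873 to 77496932. In primary neurospheres the shRNA arrays differed by 42.2% and 42.7% on the Nr2f1 probes and by 29.6% on the Nr2f2 probe, the knockdown being lower each time. In tertiary neurospheres the knockdown was lower by 55.6% and 56.9% for Nr2f1 and by 46.4% for Nr2f2. Averaged over both passages the knockdown differed from its control by -0.98 (SE 0.61) log2 units for Nr2f1 and by -0.70 (SE 0.28) for Nr2f2, with an adjusted p in limma of 0.999 for both. The control miRNA array differed from the control shRNA array by -1.08 for Nr2f1 at P0, by 0.77 at P2, and by -1.11 and -1.20 for Nr2f2, differences of the same order as the knockdown. With miR-17 the Nr2f1 difference was 0.44 at P0 and -0.13 at P2.

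**Figure D1:**
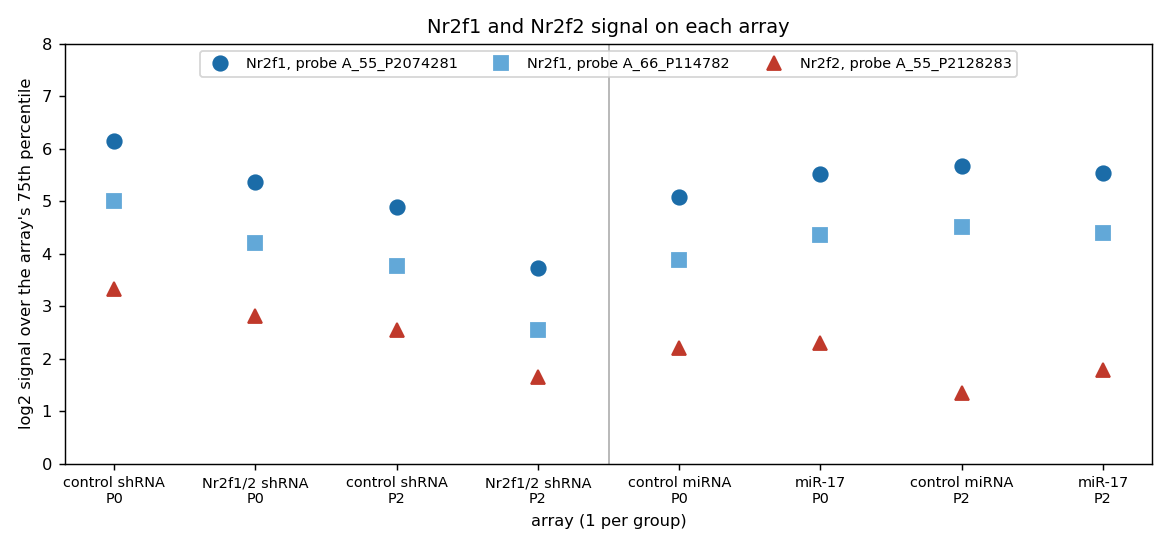
Log2 signal of the 2 Nr2f1 probes and the Nr2f2 probe over each array's 75th percentile, for the 8 arrays, with shRNA arrays left of the line and miRNA arrays right of it. Each point is 1 array, and all 3 probes lie lower with the Nr2f1/2 shRNA than with the control shRNA at both passages.

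The next comparison asked which genes differed between tertiary and primary neurospheres whatever the vector. Astrocyte and oligodendrocyte genes were higher in tertiary neurospheres and proneural and cell cycle genes in primary ones, by list tests with a preset correlation. These were lost with an estimated correlation, a form that uses only 3 residual degrees of freedom (adjusted p = 0.776 to 0.795 in camera). Bcan, the proteoglycan brevican, rose 226-fold with passage (log2 7.82, SE 0.66, adjusted p = 0.0305 in limma). Scrg1 rose at least 533-fold, Gpr17, a receptor of oligodendrocyte precursors, at least 352-fold, S100b at least 160-fold, and Ccdc80 at least 146-fold, each being not well above background on any primary array. Serpina3n, Itih3, Gpr179, Kcnj16 and the astrocyte receptor gene Ntsr2, also dim on all 4 primary arrays, rose at least 78.8-, 53.9-, 43.2-, 42.7- and 55.6-fold. Plxnb3 rose at least 90.1-fold, with 1 of 4 primary arrays well above background, and Cidea at least 117-fold with 2 of 4. In the other direction, the homeobox gene Dbx1 fell by 5.85 log2 units (SE 0.89, adjusted p = 0.0419 in limma), and Neurog2, a proneural factor, fell by 5.55 with 3 of 4 tertiary arrays well above background. Robo3, Cartpt and Rspo2, measured on all 4 tertiary arrays, fell by 4.99, 4.79 and 4.52. Mir124-2hg fell at least 25.2-fold, Gsx2 at least 25.1-fold and Phox2a at least 24.4-fold, each with 2 of 4 tertiary arrays above background. Nhlh2 fell at least 24.5-fold with 3 of 4, and Tfap2e at least 12.7-fold with 1 of 4. Prdm12 was 4.96 log2 units lower. Its signals of -7.13 and -5.68 on the tertiary control miRNA and miR-17 arrays lay below those arrays' lowest signals well above background.

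The median of all genes moved by -0.21 log2 units with passage, and by -0.02 after quantile normalization, so list medians in this paragraph and the next were taken relative to it unless given as measured. The astrocyte list stood 4.25 above, with 10 of 20 members risen, 18 when adjusted over the list alone (adjusted p = 1.43e-10 in camera). Among them S100b and Ntsr2 rose as given above, while Gfap, the astrocyte filament gene, was 7.23 (SE 1.67) log2 units higher with an adjusted p of 0.0606 in limma, and Aqp4 was 5.92 (SE 1.29) higher. In the oligodendrocyte lineage 8 of 20 members rose, 13 when adjusted over the list alone, with a list median 3.04 above (adjusted p = 4.39e-09 in camera), Cnp rising 47.9-fold and Omg at least 34.5-fold, the latter with 1 of 4 primary arrays above background. Of 14 gliogenic regulators 7 rose, and when adjusted over the list alone 8 rose and 1 fell (median 2.25 above, adjusted p = 4.05e-06 in camera), led by the nuclear factor I genes Nfix at 42.6-fold, Nfia at 6.77-fold and Nfib at 5.63-fold, and Lhx2 was 2.55 log2 units lower with an adjusted p of 0.0503 in limma. BMP and TGF-beta genes (5 of 22 rose and 1 fell, 12 and 2 over the list alone, adjusted p = 5.72e-05 in camera) included Bmpr1b at 14.5-fold and Tgfb2 at 10.4-fold. JAK-STAT genes (3 of 16 rose, 7 over the list alone, adjusted p = 0.000141 in camera) included Socs3, up by 3.42 log2 units, and the cytokine receptor Osmr at least 7.46-fold. Neural crest and mesenchyme genes (5 of 21 rose and 3 fell, 10 and 3 over the list alone, adjusted p = 0.00182 in camera) included Col1a1, up 15.1-fold, Postn, up 12.7-fold, and Tfap2b, which fell by 3.37. Interferon response genes (2 of 24 rose and 1 fell, 6 and 1 over the list alone, adjusted p = 0.00192 in camera) included Ifit3 at least 17.7-fold and Ifit2 at least 5.95-fold. The interferon list median, 0.82 as measured, was 0.46 with the 5 members dim at P0 set at their bound. With an estimated correlation none of these 7 lists held, with adjusted p = 0.776 for 6 of them and adjusted p = 0.783 for the interferon genes in camera.

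Among lists that were lower in tertiary neurospheres, 9 of 26 proneural and neurogenesis genes fell, 20 when adjusted over the list alone (median -2.18, adjusted p = 1.61e-05 in camera), among them Neurod1, at least 10.8-fold with 3 of 4 tertiary arrays above background, and Neurod4, at least 4.66-fold. All 27 cell cycle genes were lower, none passed over all genes and 25 passed when adjusted over the list alone (median -2.24, adjusted p = 3.76e-06 in camera), as with Mki67 at -3.07 (SE 0.84) and Bub1 at -3.19 (SE 0.80). Of 15 early-stage temporal factors 3 fell, 13 over the list alone (median -1.55, adjusted p = 0.000173 in camera), and the growth-associated RNA-binding genes Igf2bp1, at least 17.1-fold lower with 3 of 4 tertiary arrays above background, and Lin28b, at -3.42 (SE 0.87), had adjusted p of 0.0717 and 0.0670 in limma. Interneuron and other subtype genes included 5 that fell and 1 that rose among 30, 17 and 1 over the list alone (median -1.08, adjusted p = 0.000563 in camera), with Lhx1 down by 3.68 and Lhx5 by 3.22. Forebrain and midbrain genes (3 of 24 fell, 8 over the list alone, adjusted p = 0.0219 in camera), dorsoventral patterning genes (4 of 28 fell and 1 rose, 7 and 2 over the list alone, adjusted p = 0.0243) and surface ectoderm and choroid genes (1 of 13 fell, 6 over the list alone, adjusted p = 0.0275) included Fezf1 at -3.70, Pax7 at least 6.05-fold lower, and Cldn6 at least 2.87-fold lower with 1 of 4 tertiary arrays above background. Pluripotency genes, which would mark remaining stem cells, also fell as a list (6 of 19 fell and 1 rose, 10 and 1 over the list alone, median -1.21, adjusted p = 0.0212 in camera), among them Nr0b1, at least 9.19-fold with 2 of 4 tertiary arrays above background. With an estimated correlation these 8 lists had adjusted p = 0.776 to 0.795 in camera, so none held. The other 12 lists did not pass in camera: motor neuron (adjusted p = 0.0866), p53 response (0.0583), hypoxia and glycolysis (0.0710), reported miR-17 targets (0.275), Hox (0.305), Nr2f family and unfolded protein (0.419 each), neuron (0.425), endothelial, blood and microglia (0.529), mesoderm and endoderm (0.596), Notch (0.696), and neural stem and progenitor genes (0.742). For 3 of these the signs differed, with values as measured: the miR-17 target median was 0.14 with a mean of -0.04, the Nr2f family median was -0.27 with a mean of 0.01, and the neural stem median was -0.33 with an upward test direction.

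In all, 1317 of 27255 genes passed limma with condition as a block, 697 higher and 620 lower in tertiary neurospheres, and 10892 had an unadjusted p under the threshold. Across genes, 49.3% moved the same way in all 4 pairs of arrays, where chance gives 12.5%. The count rested on the full set of arrays: without either array of the control shRNA, control miRNA or miR-17 condition 0 genes passed, and without either Nr2f1/2 shRNA array 4786 did, of which 1290 were among the 1317. Normalization moved the balance, with 66.5% of calls higher after quantile normalization and 30.6% after normexp background correction, against 52.9% here.

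The knockdown was then compared with its control shRNA. In tertiary neurospheres the knockdown array had lower glial genes and higher cell cycle and forebrain genes than its control, and in primary neurospheres the same lists differed little. At P0, however, only 15 of 20 astrocyte, 16 of 20 oligodendrocyte and 17 of 24 interferon genes were well above background on either shRNA array. S100b, Ntsr2 and Gpr17 were dim on all primary arrays, so a fall of such genes at P0 could not be seen. Of 20 astrocyte genes 18 were lower by at least 2-fold at P2 and none at P0, with list medians of -2.33 and -0.09, and S100b was 59.4-fold, Ntsr2 48.0-fold, Gfap 25.6-fold and Aqp4 21.2-fold lower. Of 20 oligodendrocyte genes 14 were at least 2-fold lower at P2 (median -2.91, or -2.42 with dim members at their bound), with Gpr17 429-fold lower and Bcas1 and Sox10 50.8- and 23.3-fold lower. All 27 cell cycle genes were at least 2-fold higher at P2 (median 2.21), such as Top2a at 7.04-fold and Mki67 at 5.98-fold, against a median of 0.15 at P0. Forebrain and midbrain genes were higher at P2 (14 of 24 at 2-fold, median 1.18), with the signalling gene Fgf8 50.8-fold and the eye-field gene Six6 21.4-fold higher, and Fezf2 7.82-fold higher. Interferon response genes were lower (13 of 24 at 2-fold, median -1.14), Ifit3 by 30.9-fold and Xaf1 by 9.65-fold. Each of these P2 medians lay at percentile 0 or 100 of 10000 random lists matched on level, as a description of these arrays. The same lists differed between the control miRNA and control shRNA arrays at P2 as well, by 1.46 for astrocyte, 0.53 for oligodendrocyte, -1.01 for cell cycle, -0.22 for forebrain and 0.16 for interferon genes.

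Single genes that differed in the given direction at P2 and not at P0 included Isl1, a motor neuron homeobox gene, 28.7-fold higher against a log2 difference of -0.58 at P0, and Igfbpl1 and Fgf15 at 16.4- and 15.3-fold higher. Nkx2-3 was 16.6-fold and the histone gene H3c1 25.4-fold higher. Srpk3, Lims2 and the cilia gene Cfap65 were 64.3-, 57.6- and 55.4-fold lower at P2, while at P0, where neither Srpk3 nor Cfap65 was well above background on the shRNA arrays, their measured differences were 1.003 and 1.61 log2 units. At P0 and not at P2, Abcc6 was 4.30-fold and Ihh 3.53-fold higher. Egr2 was 3.19-fold higher at P0 and at -1.07 log2 units at P2, while Mixl1, Crx and Ltk were 8.76-, 6.51- and 5.63-fold lower. Several of these also differed between the control arrays at P0, Abcc6 by 3.68, Mixl1 by -5.92 and Crx by -5.17 log2 units.

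Over both passages together no gene passed limma for the knockdown, with 522 at an unadjusted p under the threshold and a smallest adjusted p of 0.999. Among genes measured on all knockdown and control arrays that differed the same way at both passages, Fgf8 was at 1.32 at P0 and 5.67 at P2, although the control arrays differed by 2.31 at P0. Inca1 was at -2.32 and -2.62, with a difference between the control arrays of -2.29 at P0, and Sspn at -1.39 and -3.25. Aqp5 was at -1.59 and -2.80, but its signal on the knockdown array at P0 lay below that array's lowest signal well above background. Wnt10a and Dhh, not well above background on either knockdown array, were at least 2.62- and 2.33-fold lower. In camera 8 lists passed: astrocyte (median -1.26, adjusted p = 3.76e-06), oligodendrocyte (-1.53, adjusted p = 3.76e-06), neuron (-0.25, adjusted p = 0.000430), interferon (-0.49, adjusted p = 0.00218) and unfolded protein genes (-0.34, adjusted p = 0.0389) were lower, and cell cycle (1.20, adjusted p = 2.22e-07), forebrain (0.53, adjusted p = 0.00481) and early-stage genes (0.56, adjusted p = 0.0230) were higher. None of the 8 held with an estimated correlation and 3 residual degrees of freedom, where the smallest adjusted p in camera was 0.776. Within these lists no member passed when adjusted over the list alone. The list of Nr2f family genes and partners had a median of -0.36 with an adjusted p of 0.0503 in camera, and its members Bcl11b and Bcl11a went the other way at P2, 6.24- and 2.92-fold higher. Medians of the neural stem (-0.03), Hox (-0.00417) and motor neuron lists (-0.14) had means of opposite sign. The other lists had an adjusted p of 0.0619 for proneural genes or above. Without the Nr2f1/2 shRNA array at P2 the medians of the astrocyte, oligodendrocyte, cell cycle, interferon and early-stage lists turned sign, to 0.12, 0.14, -0.21, 0.20 and -0.0105, and without the control shRNA array at P0 that of the unfolded protein list turned to 0.0842.

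**Figure D2:**
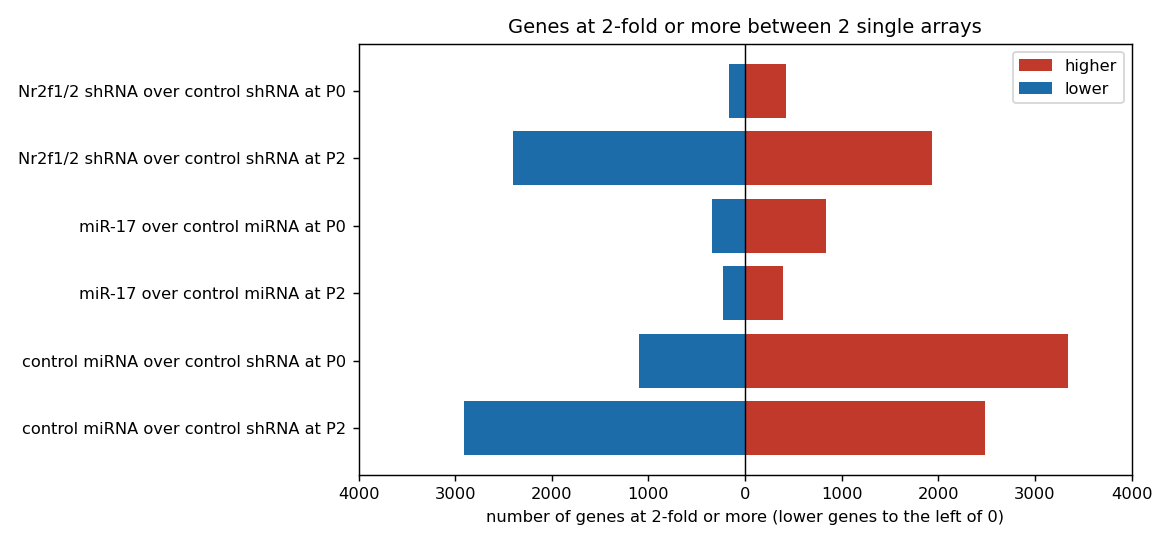
Number of genes at 2-fold or more between 2 single arrays of the same passage, with genes higher in the first-named array right of 0 and lower genes left of 0. The knockdown at P2 had 4338 such genes, and the pairs of control arrays had 4438 at P0 and 5398 at P2.

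At 2-fold or more, 586 genes differed between knockdown and control in primary neurospheres, 420 higher and 166 lower. In tertiary neurospheres 4338 did, 1935 higher and 2403 lower. The control miRNA and control shRNA arrays, which carried no manipulation of Nr2f1, Nr2f2 or miR-17, differed in 4438 genes at P0 and 5398 at P2. The interaction of knockdown and passage called 0 genes in limma, with 1085 at an unadjusted p under the threshold, so the difference between passages did not pass.

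miR-17, a microRNA of a cluster expressed in proliferating progenitors, was compared with its control miRNA. The arrays with miR-17 had higher neuronal and lower gliogenic list medians than the control miRNA arrays. Of 25 neuron genes 23 were higher at P0 and 20 at P2, with medians of 0.38 and 0.65, and Elavl4 was 2.01- and 2.25-fold higher while Myt1l and Dcx were 2.50- and 2.44-fold higher at P2. Among proneural genes (medians 0.63 and 0.48) Neurod4 was 6.20-fold and Neurog2 2.21-fold higher at P0, and Ebf3 2.13- and 3.21-fold higher at P0 and P2. Among motor neuron genes Lhx3 was 4.70-fold higher at P0 and the acetylcholine transporter gene Slc18a3 2.69-fold higher at P2. Interneuron genes included Tal1, 3.70- and 2.82-fold higher at P0 and P2, and Gata2, 2.68- and 2.62-fold higher. Gliogenic regulators were lower at both passages (medians -0.56 and -0.33), with Nfia 1.80- and 1.75-fold lower. Reported miR-17 targets had medians of -0.08 and -0.25, at percentiles 77.1 and 0.01 of random lists matched on level. Rbl1 was 1.84-fold lower at P0, Zbtb4 1.72-fold and Jak1 1.57-fold lower at P2, and Dusp2 2.21-fold higher at P0. Under knockdown at P2, without miR-17, the target median was -0.20. The control miRNA array differed from the control shRNA array in this list by -0.23 at P0 and 0.23 at P2. Hox genes were higher at P0 (14 of 22 at 2-fold, median 1.29, or 1.40 over 18 members with dim ones at their bound) and not at P2 (median -0.23), with Hoxb2 6.30-fold and Hoxc6 6.22-fold higher at P0. Hypoxia and glycolysis genes were lower at P0 (8 of 16 at 2-fold, median -0.92), with Adm 6.53-fold and Slc2a1 2.84-fold lower, and had a median of 0.33 at P2. The control miRNA array differed from the control shRNA array in the Hox list by 1.20 at P0 and 1.30 at P2, and in the hypoxia list by 0.75 and -0.35. For neuron genes it differed by -0.50 and -1.97, larger than the miR-17 medians, and at P2 by -0.64 for proneural, -1.35 for motor neuron, -1.02 for interneuron and 0.66 for gliogenic genes.

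No gene passed limma for miR-17 over both passages, with 271 at an unadjusted p under the threshold and a smallest adjusted p of 0.9998. Among genes measured on all miR-17 and control arrays and moving the same way at both passages, Mgp was at 2.11 and 1.51, Car3 at -1.99 and -1.85, Lefty1, a Nodal antagonist, at -1.30 and -1.65, and Slc6a11 at -1.14 and -0.97 log2 units. The control miRNA array differed from the control shRNA array at P0 by 0.90, 3.85, 0.45 and 0.81 for these genes in that order. At P2 it differed by 1.45, 0.49, 0.28 and -0.03. In camera 11 lists passed: neuron (median 0.53, adjusted p = 2.55e-05), Hox (0.66, adjusted p = 0.000141), proneural (0.43, adjusted p = 0.000143), interneuron (0.40, adjusted p = 0.00100), crest and mesenchyme (0.36, adjusted p = 0.00182) and motor neuron genes (0.43, adjusted p = 0.00337) were higher. Gliogenic (-0.35, adjusted p = 0.00182), hypoxia (-0.27, adjusted p = 0.00192), reported target (-0.16, adjusted p = 0.00536), neural stem (-0.07, adjusted p = 0.0114) and cell cycle genes (-0.31, adjusted p = 0.0468) were lower. None of the 11 held with an estimated correlation and 3 residual degrees of freedom, where the smallest adjusted p in camera was 0.776. No member passed when adjusted over its list alone. The other 16 lists had an adjusted p of 0.0720 or above, and the astrocyte median (0.03) and the BMP and TGF-beta median (0.00167) had means of -0.09 and -0.04. Without 1 array, list medians turned sign for the cell cycle (to 0.67 and 0.40), hypoxia (0.25), motor neuron (-0.15) and Hox genes (-0.08 and -0.12). At 2-fold or more 1177 genes differed at P0, 836 higher and 341 lower, and 620 at P2, 387 higher and 233 lower. The interaction of miR-17 and passage called 0 genes in limma, with 298 at an unadjusted p under the threshold. Genes that differed in the given direction at 1 passage only included Esm1, Heyl and Cd34, 7.20-, 6.99- and 6.33-fold higher at P0, Six6, 16.5-fold lower at P0, Nts and Foxo4, 5.66- and 4.89-fold higher at P2, and Gjb6, 4.38-fold lower at P2. The Foxo4 signal of -6.89 on the control miRNA array at P2 lay below that array's lowest signal well above background. Its fold is thus not a measured one. The control arrays themselves differed at P0 by 3.07, 0.89, 2.10 and 2.18 log2 units for Esm1, Heyl, Cd34 and Six6. At P2 they differed by -3.10, -1.04 and 1.53 for Nts, Foxo4 and Gjb6.

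**Figure D3:**
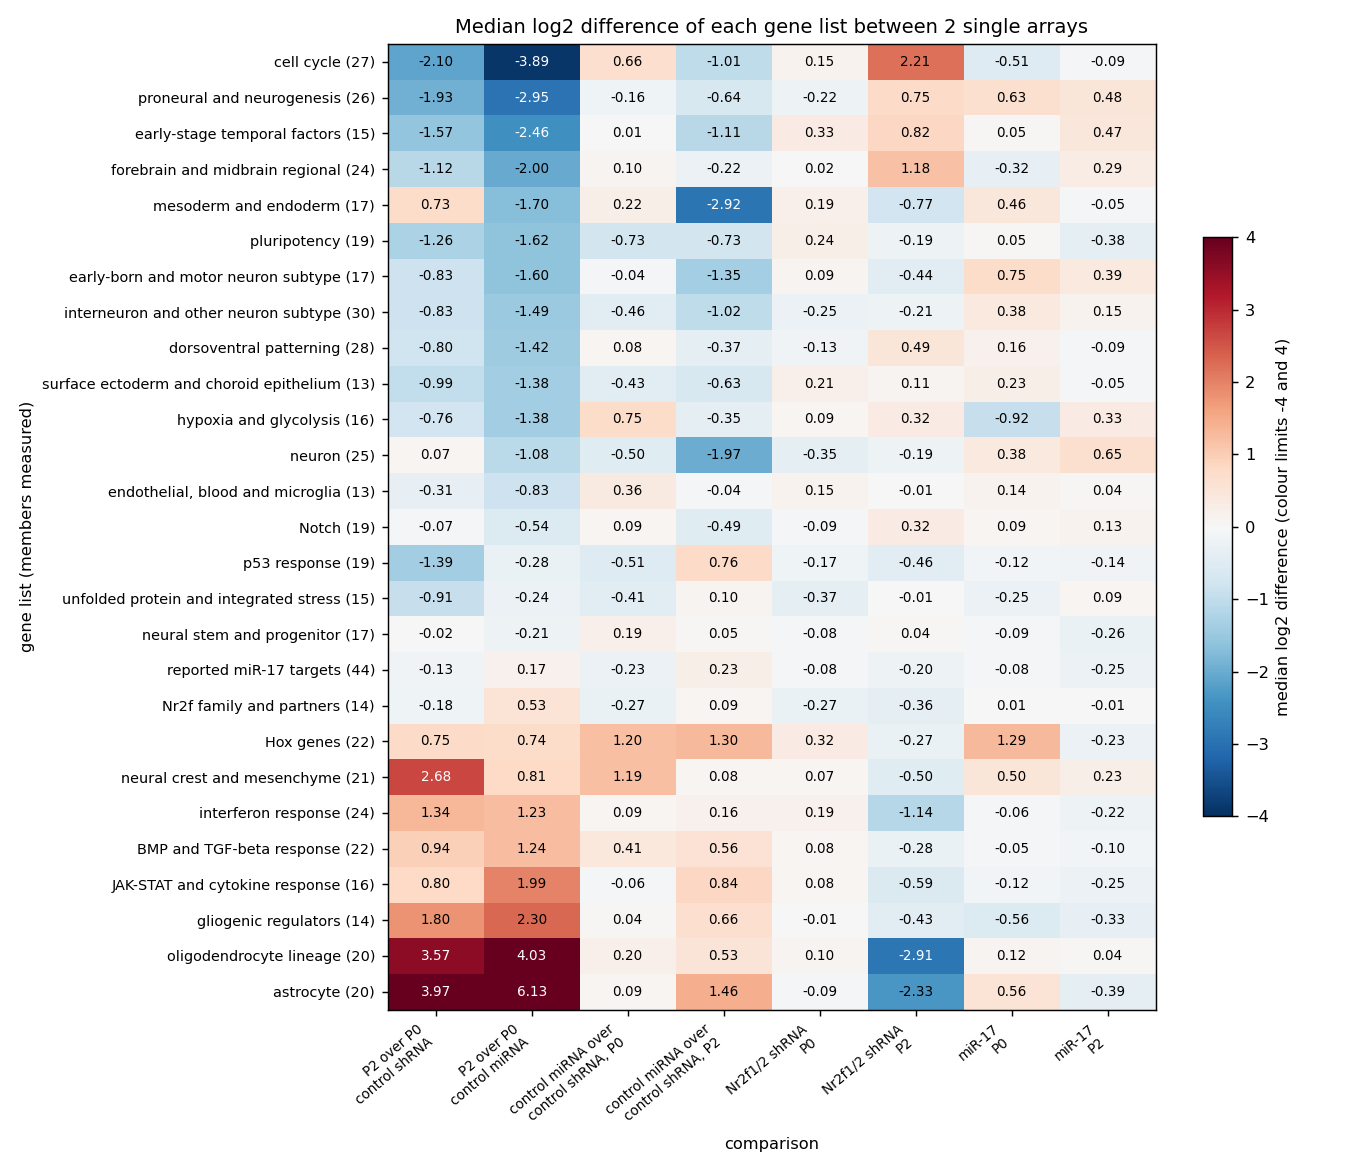
Median log2 difference of each fixed gene list in 8 comparisons between 2 arrays, with the number of measured members beside the list name and colour limits at -4 and 4. The knockdown at P2 shows -2.33 for astrocyte and 2.21 for cell cycle genes, opposite in sign to 6.13 and -3.89 for P2 over P0 in the control miRNA pair, which shares no array with it. The control shRNA passage pair shares its P2 array with the knockdown at P2, which by itself favours opposite signs. Members not well above background enter at their measured value.

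A further comparison asked whether either manipulation of tertiary neurospheres moved passage genes back toward their primary level. The genes were those at 2-fold or more in the control pair of the other vector system, so that no array was shared. Under knockdown at P2, 82.1% of 9801 such genes lay toward their P0 level, with a median move of 0.60 log2 units, 2901 at 2-fold toward and 235 away. Under knockdown at P0 the median was 0.14 and 67.1% of 9344 lay that way. With miR-17 at P2 the median was 0.07 and 57.3% of 5712 lay toward P0. With miR-17 at P0 it was -0.07, with 44.9% of 5785.

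Of 760 measured transcriptional regulators, 194 differed by 2-fold or more the same way with passage in both control pairs, 63 higher and 131 lower at P2. Under knockdown at P2, 133 of them (68.6%) moved back by at least 1.5-fold and 4 moved away, and with miR-17 53 (27.3%) moved back and 9 away, where over all genes 80.8% and 15.8% moved back. Sharing the control array gives such moves by itself: simulated unchanged groups gave 30.3% back and 18.7% away for the knockdown and 27.5% and 22.9% for miR-17. The miR-17 share back was near the simulated one. The simulated spread came from the additive fit, whose residual holds any real interaction, and both measured shares away lay below the simulated ones. The simulation therefore cannot set a no-change share for these arrays. The miR-17 folds below are differences between 2 arrays. In a comparison added after seeing the data, with regulators taken from the other vector system's control pair alone, 180 of 330 (54.5%) moved back under knockdown and 17 away, and 56 of 236 (23.7%) moved back with miR-17 and 22 away. Over all genes these shares were 50.9% and 12.2%. Regulators back under both manipulations numbered 40, against 36.3 for independent sets. Among these 40, Isl1 was 28.7-fold higher under knockdown and 1.58-fold higher with miR-17, the cut-homeobox genes Onecut2, by 3.42 and 1.22 log2 units, and Onecut1, 9.37- and 2.07-fold, and the cortical genes Fezf2 7.82- and 1.57-fold and Bcl11b 6.24- and 1.69-fold. Tal2 was 5.20- and 3.46-fold, Dlx2 4.93- and 1.81-fold, Dbx1 6.44- and 2.03-fold, Sp5 9.43- and 1.79-fold, E2f7 6.16- and 1.56-fold and Prdm8 4.69- and 1.58-fold higher, and Grhl3 17.4-fold higher under knockdown. Under knockdown the dorsal spinal factor Olig3 and the forebrain factor Lhx8 were higher by at least 5.54 and 5.01 log2 units, with 1 of 2 arrays well above background. Nkx2-9, Neurog2 and Onecut3 were 15.9-, 13.2- and 11.0-fold higher, and the oligodendrocyte regulators Sox10 and Sox8 were 23.3- and 11.4-fold lower. With miR-17 Scrt1, Lhx1, Lhx5, Ebf3 and Lhx9 were 3.66-, 3.55-, 3.37-, 3.21- and 3.17-fold higher, and Gata2, Ebf1, Insm1 and Tfap2b 2.62-, 2.41-, 2.29- and 2.29-fold higher.

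**Figure D4:**
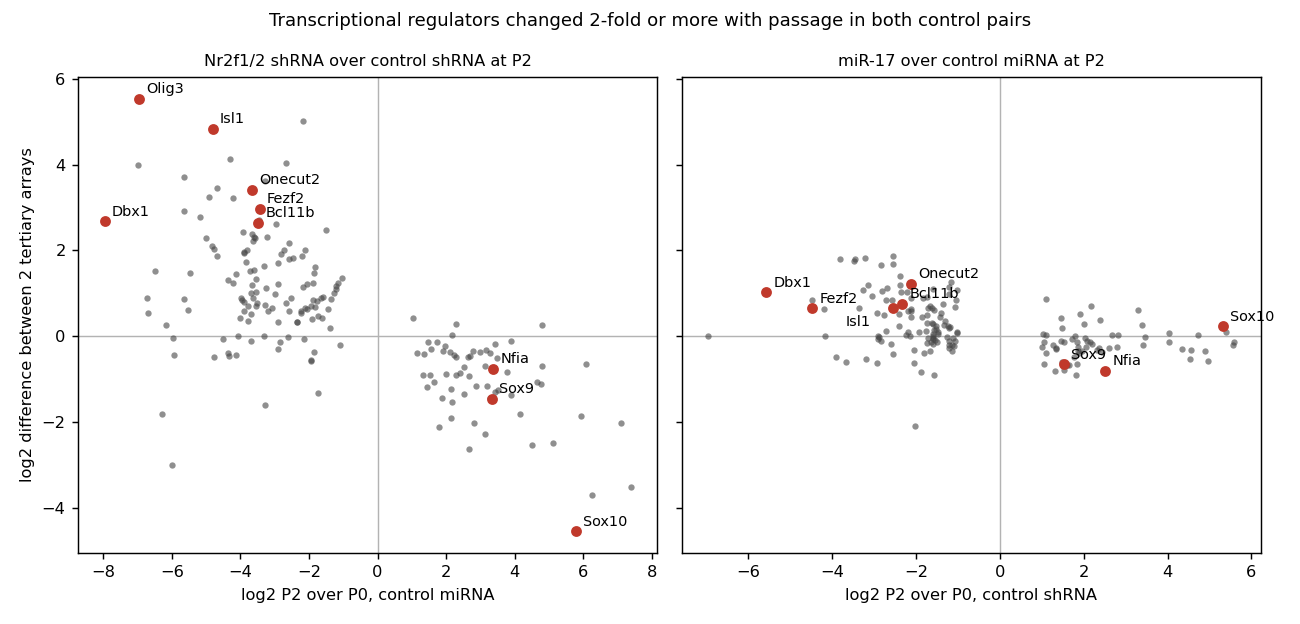
Log2 difference between 2 tertiary arrays (y axis) against log2 P2 over P0 in the other vector system's controls (x axis) for regulators changed with passage in both control pairs. Under knockdown 133 of 194 regulators lie back toward P0 by 1.5-fold, and with miR-17 53. The miR-17 share was no higher than in simulated unchanged groups, which cannot set a no-change share for these arrays. Regulators dim on both tertiary arrays are not drawn, and those dim on 1 are drawn at their bound.

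The knockdown and miR-17 effects were set against each other across genes, which are not independent replicates. Pearson's r was 0.16 at P0 (Spearman's rho 0.19) and 0.12 at P2 (rho 0.14). At P0, 57 genes were at least 2-fold higher under both where independent lists would give 9.83, 8 were lower under both where they would give 1.88, and 29 moved in opposite directions where they would give 8.77. At P2 the genes higher under both were 4.01 times the 25.7 of independent lists, 96 were lower under both where they would give 20.4, and 51 moved in opposite directions where they would give 50.1. No control array was shared between them. Both comparisons, however, set slide row 2 against row 1 at P0 and row 4 against row 3 at P2. A row effect therefore cannot be told apart from a shared response.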

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

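The tests of stage difference, array scaling and other splits of the arrays were chosen only after the result was seen.

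For mesoderm and endoderm genes the median passage difference was 0.73 in the control shRNA pair and -1.70 in the control miRNA pair. Nr2f1 moved with passage by -1.26 in the control shRNA pair and by 0.60 in the control miRNA pair. Hox genes had a median passage difference of 0.74 in the control miRNA pair and -0.91 in the miR-17 pair. With dim members at their bound these Hox medians were 0.44 over 21 members, which is under 1.5-fold, and -0.91 over 22. These 3 differences between groups were not tested as such, and each rests on 1 array per group. For the Hox genes the contrast is the interaction of miR-17 and passage, which called 0 genes in limma and was not run on lists.

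Passage genes lay nearer their primary level with the Nr2f1/2 shRNA at P2, with a median move of 0.60 log2 units. Array scaling was argued against, since the move was 0.6174 after quantile normalization. For a single share of cells held at the primary stage, genes higher at P2 implied a median of 85.5% of primary-stage RNA and genes lower at P2 62.3%. The difference of 23.14 percentage points did not meet the prediction written before, which asked for closer shares. The quartiles overlapped (69.6% to 96.6% and 29.9% to 96.2%). The control shRNA arrays both helped choose the genes and entered the shares. This explanation was therefore not decided. A difference in stage between separately grown cultures cannot be told apart from the knockdown: over genes of the miR-17 pair, the shift between the control arrays at P2 was 1.102 times that of the knockdown, while over genes of the knockdown pair it was 0. An effect of the shRNA itself stays open as a hypothesis and was not separable with 1 array per group.

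The control shRNA and control miRNA cultures differed by 2-fold in 4438 genes at P0 and 5398 at P2. Slide column was argued against as a cause for bright probes: 8 spike-in probes differed between columns by an SD of 0.1388 log2 units. That SD averages the 4 arrays of each column, while the genes' SDs of 1.05 and 1.03 each compare 2 single control arrays. At P0 the dimmest of the 8 read 6.38 log2 units with the control shRNA and 7.37 with the control miRNA. At P2 it read 6.57 and 6.60. Dimmer spike-in probes were left out, so a column difference at low signal stays open. Whether vector, culture or virus set the control cultures apart was not tested.

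The count of 1317 passage genes was compared with other splits of the 8 arrays into 4 and 4. With condition as a block, 3 of 32 splits called at least as many, so chance was not excluded there, and the highest other split called 7441. The 2 other splits that called more part only the miRNA arrays by passage, which points to a structure of the samples. Under the block they are the same contrast with opposite sign, and they hold the passage difference itself, so they do not measure chance. Among the 8 splits that part all 4 conditions the highest other called 0. Without the block, 1 of 35 splits, the passage split itself, called as many as 3929 genes, and the highest other called 1, but those splits ignore the pairing by condition, and the 8 that keep it are too few for a share under 0.05.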

How the results depend on the processing

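The regulators taken from the other vector system's control pair were added after seeing the data. Counts of 0 for knockdown, miR-17 and both interactions stayed at 0 in limma under all alternatives run, and Nr2f1 and Nr2f2 kept their direction under knockdown. For untested values, moves within 1.5 times the value were taken as unchanged. The 2-fold counts and the bounds depend on signal over background, which limits dim genes. Slide as a block, the seed match and the interaction with an array left out were not run. The cause of the changes below was not tested, except that leaving out an array drops its condition from the passage contrast.

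Passage calls were 7066 with normexp, 3691 with probes above background on all 8 arrays, 4303 with a trended prior, 3929 without the block and 0 with the control conditions only, where 5766 genes had an unadjusted p under the threshold. Leaving out 1 array gave 0 to 4786. With normexp the 2-fold counts were 106 (knockdown P0), 334 and 147 (miR-17 P0 and P2) and 1961 and 3142 (controls). With the all-array filter they were 213, 579 and 330, and 2349 for the controls at P0. At 1.5-fold they were 2354 and 9456 for the knockdown, 5333 and 2932 for miR-17 and 9331 and 10907 for the controls, and at 3-fold 130 and 1792, 196 and 92, and 1888 and 2135. The move toward P0, defined by both control pairs, was 1.18 and 0.0583 for the knockdown at P2 and P0, and 0.175 and -0.0210 for miR-17, but these genes share a control array with the comparison, which by itself gives a move back at P2 and away at P0. Over 4-fold genes it was 0.908 for the knockdown at P2, and quantile normalization turned miR-17 at P0 to 0.00625. Without a filter the correlation at P0 was 0.0922.

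With an array left out, list medians under knockdown ranged from -2.76 to 0.12 for astrocyte, -3.10 to 0.14 for oligodendrocyte, -0.21 to 2.60 for cell cycle, -1.31 to 0.20 for interferon, -0.0105 to 1.28 for early-stage, -0.32 to 1.13 for proneural, -0.47 to 0.75 for dorsoventral and -0.73 to 0.0842 for unfolded protein genes. With miR-17 they ranged from -1.15 to 0.67 for cell cycle, -0.90 to 0.25 for hypoxia, -0.15 to 1.21 for motor neuron, -0.12 to 1.30 for Hox, -0.33 to 0.28 for unfolded protein and -1.54 to 0.83 for astrocyte genes. No list call held with an estimated correlation, 15 for passage, 8 for knockdown and 11 for miR-17. That form also uses only 3 residual degrees of freedom, so the losses cannot be put down to correlation alone. With miR-17 the neural stem list, whose estimated correlation was -0.03, went from an unadjusted p of 0.0038 to 0.0526 in camera.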

Other observations

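The test of cilia genes used a family list written only after Cfap65 and Foxj1 were seen to be lower.

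In tertiary neurospheres with the Nr2f1/2 shRNA, genes of motile cilia were low. Cfap65 differed from the control shRNA array by -5.79 log2 units and Foxj1, the master regulator of motile cilia, by -2.62. Among the 63 other motile cilia genes of the list the median was -1.57 at P2, 40 of them at least 2-fold lower, which lay at percentile 0 of random lists matched on level. Dnah6, an axonemal dynein, was at -5.08, Cfap52 at -4.65 and Cfap45 at -3.52, these 3 being named after their values were seen. At P0 the median was -0.02. With passage, the control shRNA pair gained 1.80 and the control miRNA pair 1.05, while the knockdown pair gained 0.08. With miR-17 the medians were 0.13 at P0 and 0.10 at P2.

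A candidate explanation is a loss of motile cilia genes as a group under knockdown at P2. The median of -1.568 over the other members met the prediction written before that test, though after Cfap65 and Foxj1 were seen. The list also rose with passage in both control pairs, and 82.1% of 9801 passage genes lay toward P0 under knockdown at P2. Random lists matched on level only cannot separate a loss particular to cilia genes from that general move. The control miRNA array was also lower than the control shRNA array at P2, by 0.50 with 20 genes at 2-fold, so a difference between cultures stays open.

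Across genes, the control miRNA and miR-17 passage pairs had r = 0.917, the control shRNA and control miRNA pairs 0.609, and the control shRNA and Nr2f1/2 shRNA pairs 0.58. Genes are not independent replicates.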
